A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

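New histone H3 was followed by ChIP-chip in Schizosaccharomyces pombe. Per the labels, the cells carried cdc25-22, were arrested at G2/M at 36 °C for 4 h after growth at 26 °C, and received 1 µM β-estradiol for 2 h so that Cre recombinase exchanged the HA tag of H3 for a T7 tag. H3-T7 chromatin was immunoprecipitated after fixation with 1% formaldehyde, and its DNA was labelled with Cy5, while whole-cell extract DNA (the input) was labelled with Cy3. Both were hybridized to a 60-mer tiling array with 1 probe every 300 bp. The design crosses 2 genotypes (wt and clr3-CDx2) with 2 tethering states. In the ON state TetR-Clr4 was made in thiamine-free medium for 20 generations in cells with a tetO-ade6+ reporter. In the OFF state the medium held 5 µg/ml thiamine and 2.5 µg/ml tetracycline. Each of the 4 groups is 1 array. The nature of the CDx2 allele and the site of tetO-ade6+ in the genome are not given in the sources used here. With 1 array per group there were no replicates to pair. The limma fit described below compares the levels of each factor within the levels of the other.

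The authors used Agilent Feature Extraction, and per the file headers the version was 12.0.3.1. The deposited scanner files hold processed signals as intensity, background-subtracted and dye-normalized within each array by a linear factor. They also hold a log10 ratio of the channels, per the file headers, which was not used here. Other deposited columns are flags of 0 or 1, used to leave out spots. The deposited series matrix holds log2 of Cy5 over Cy3 processed intensity, without further centring, for 100% of non-control spots within a tolerance of 1e-6. Per the file headers, multiplicative detrending was applied to both channels on the OFF arrays and to Cy3 alone on the ON arrays. All 4 arrays lay on 1 slide.

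Each array has 42968 spots, of which 1417 are controls. Spots marked as outliers on any array (531) were left out, and 41020 probes were used, 40740 of them on chromosomes I to III. The value of a probe is log2 of Cy5 over Cy3 processed signal, centred on the array median. The median Cy3 signal was 7066 to 13925 units against a local background of 37 to 43, and the median Cy5 signal was 4442 to 7688 against 54 to 64. At most 5 spots per array were not well above background and no spot was saturated.

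The genome build of the array coordinates is not given in the sources used here, and coordinates printed are those of the array. Genes were taken by name from assembly ASM294v3 and placed on the array by a match of the input signal to the GC content of the assembly, separately for each chromosome arm. The match had a correlation of 0.231 to 0.327 against at most 0.040 at other offsets. In 12 simulated placements the largest error was 35 bp. Over blocks of the real arms the offset had an SD of 34 to 94 bp. The match and the simulations left out the outer part of each arm, subtelomeres included. Genes there were placed by the offset of the rest of the arm, which was not checked at the ends. A gene is the mean of the probes whose midpoint lies in it, and the 4601 protein-coding genes with at least 3 probes were used. Probes with the suffix f or m in their name, whose meaning is not given in the sources used here, make up 79.8% of centromere probes, 50.9% of subtelomere probes and 100% of the probes of the rDNA ends.

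Lists, regions, thresholds and the rule for named genes were chosen before the data were examined. The lists were thiamine-repressed genes, purine synthesis, heterochromatin machinery, histone genes, reporter and marker loci, meiotic genes with heterochromatin islands or Mmi1 targets, heat shock genes, phosphate genes, ribosomal protein genes and subtelomeric genes. The regions were centromeres, the mating-type region, subtelomeres (50 kb at each end of chromosomes I and II), the ends of chromosome III beyond its last protein-coding gene (rDNA ends), Tf2 retrotransposons, probes within 300 bp of a tRNA gene, and 20 kb either side of ura4 and of ade6. Named genes are the 10 most positive and 10 most negative differences per comparison among genes with at least 80% of probes on the same side of 0, the 5 domains of each direction with the largest absolute sum of differences, the 10 smallest adjusted p per direction in limma, and members of the lists (of ribosomal protein and subtelomeric genes only those in the top lists, and tlh1).

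With 1 array per group no test was made for pairs. Genes that differed at least 1.5-fold were counted. A domain is a run of at least 5 probes whose running median over 5 probes differed at least 1.5-fold, without a gap over 900 bp. Region means were placed among 10000 random contiguous stretches with the same number of probes, and list medians among 10000 random lists matched in 20 bins of mean level. Percentiles describe and are not p-values. Domains called in one pair were read in the other pair, which shares no array with it. The main effects of tethering and of genotype were tested by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, additive in both factors, 1 residual degree of freedom, Benjamini-Hochberg adjusted p below 0.05). For both effects on the ratios, eBayes added 150 prior degrees of freedom pooled across genes. Small p values thus rest on a spread shared by genes, not on replicates. The same fit was made on the Cy3 channel. This fit treats the interaction of the factors as noise. Tested on simulated data with 200 changed genes, it called 86% of tethering and 79% of genotype changes of 0.5 on the log2 scale and 100% of changes of 1, and called 8 and 11 unchanged genes. The simulated noise was independent between genes and arrays, had the spread estimated by the same fit and held no interaction. In the real arrays the residual is the interaction itself, so these rates need not hold there. Planted domains of 8 probes with a shift of 0.8 were found in 72% to 92% of cases. The probe order was shuffled before planting, which removes any likeness of neighbouring probes. The rates for planted domains need not hold in the real order. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used otherwise.

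The alternatives chosen before the data were examined were normexp with an offset on median and background signals (the files have no mean signal), the series matrix values, loess within arrays, centring outside heterochromatin, scaling to an equal median absolute deviation (MAD), probes well above background, gene medians, a minimum of 1 or 5 probes, thresholds of 1.3-fold and 2-fold, running medians over 3 or 9 probes, and for limma also no term for the other factor, leaving out each array together with that term (3 arrays leave no residual for both terms), trended and robust eBayes, and probes as the unit. Added after seeing the data were background-subtracted signals without detrending, probes with no f or m suffix, removal of the GC trend in 20 bins, genes placed 150 bp to either side, the separate reading of the Cy5 and Cy3 channels, the reading of Cy5 in one genotype for genes called in the other, and subtraction of the mean mitochondrial ratio of each array at the subtelomeres.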

Results

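H3-T7 was measured on 4 arrays, 1 each for wt OFF, clr3-CDx2 OFF, wt ON and clr3-CDx2 ON cells. H3-T7 enters chromatin after the tag exchange, so its ratio to input reports new H3 present in the chromatin of arrested cells. No array measured total H3, so low incorporation of new H3 cannot be told apart from a low amount of H3. Clr4 is the histone H3 lysine 9 methyltransferase of fission yeast, and Clr3 is a histone deacetylase of the SHREC complex that acts on lysine 14 of H3. Values are log2 ratios of ChIP over input relative to the array median, and differences of values are log2 as well. There are no replicates within groups, so spreads given are SD over the probes of a region or gene. Over probes, arrays of the same tethering state correlated more (r = 0.81 for OFF and 0.81 for ON) than arrays of different states (0.69 to 0.73). These correlations are across probes, which are not independent replicates.

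The H3-T7 level was low at centromeres and at the rDNA ends. In wt OFF cells the centromeres averaged -1.61 (336 probes), 3.04-fold below the array median, and the rDNA ends averaged -1.93 (SD 0.55, 94 probes), 3.81-fold below. Subtelomeres averaged -0.56 (SD 0.62, 576 probes), the mating-type region -0.34 (SD 0.57, 98 probes) and tRNA gene probes -0.46 (264 probes), while Tf2 retrotransposons, mobile elements in many near-identical copies, stood at 0.62 (73 probes). In clr3-CDx2 OFF cells the centromeres stood at -1.36, rDNA ends at -1.80, subtelomeres at -0.21, the mating-type region at -0.34, tRNA gene probes at -0.40 and Tf2 at 0.46. In wt ON cells the same regions stood at -1.27, -0.81, -0.79, -0.15, -0.43 and -0.01. In clr3-CDx2 ON cells centromeres stood at -1.26, subtelomeres at -0.30, the mating-type region at 0.04, tRNA gene probes at -0.33 and Tf2 at 0.24, and rDNA ends were 2.21-fold below the median. The centromere level was below that of each of 10000 random sets of stretches on every array. Its size depended on the starting signal: with normexp it was -0.91 in wt OFF cells.

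**Figure D1:**
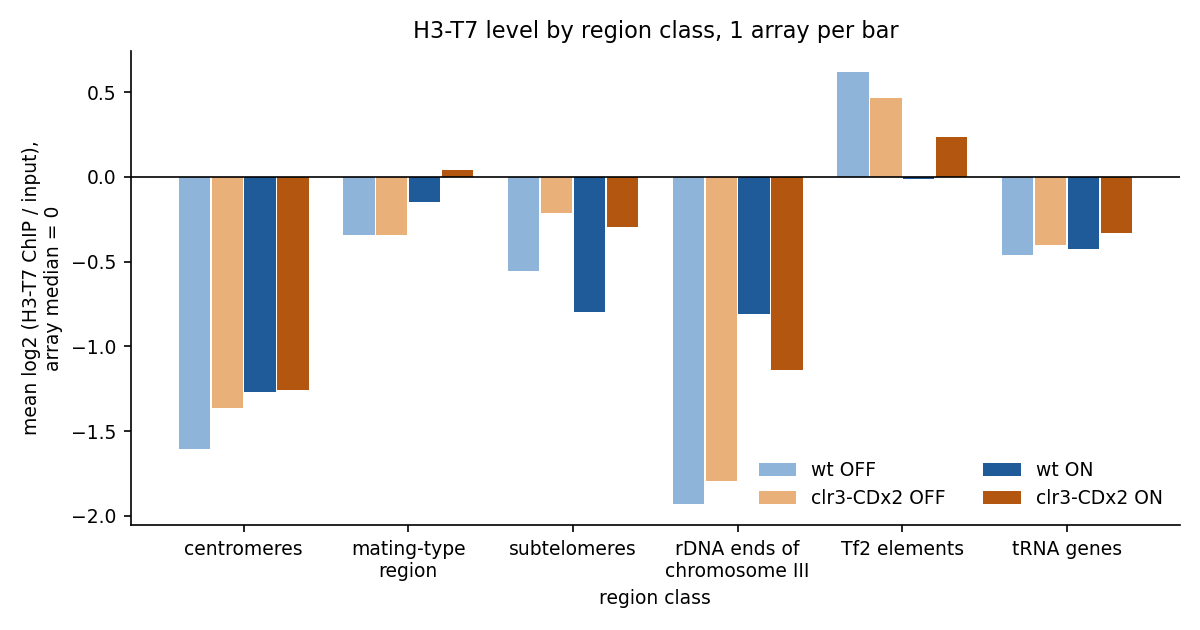
Mean log2 ratio of H3-T7 ChIP over input (vertical axis, array median at 0) for 6 region classes, with 1 bar per array. The rDNA ends stand at -1.93 and -1.80 on the OFF arrays and at -0.81 in wt ON.

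The comparison of wt ON with wt OFF asks what tethering of Clr4, together with its change of medium, does to H3-T7 in cells with unmodified clr3. The genes with the highest values in ON included fba1 (fructose-bisphosphate aldolase, 1.59, SD 0.29 over 4 probes), adh1 (alcohol dehydrogenase, 1.38), eno101 (enolase, 1.35, Cy3 input part -0.61) and tdh1 (glyceraldehyde-3-phosphate dehydrogenase, 1.18). Genes of phosphate uptake followed, with pho1 (acid phosphatase) at 1.27, pho84 (phosphate transporter) at 0.94 and tgp1 at 0.36 (list median 0.94, percentile 99.95). H3-T7 was lower in ON at genes near chromosome ends, among them fah1 (-1.51), SPAC869.01 (-1.09), ftm1 (-1.07, Cy3 part 0.58) and grt1 (-1.05), and at gid2 (-1.15), which encodes a subunit of the GID ubiquitin ligase. In all, 105 of 4601 genes were at least 1.5-fold higher and 79 at least 1.5-fold lower, 20 of the lower ones subtelomeric.

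Several gene lists were higher in wt ON. The median of the 9 thiamine-repressed genes was 0.39 (percentile 99.8 among random lists), led by SPBC530.07C (1.48), bsu1 (0.73) and thi4 (0.60), while thi2 stood at -0.03 and SPCC18B5.05C at -0.20. The 54 measured ribosomal protein genes had a median of 0.25, above each of 10000 random lists, with 42 above 0. Medians were 0.45 for 9 heat shock genes (percentile 94.8), 0.36 for 7 histone genes (96.7; -0.22 with at least 5 probes per gene), 0.07 for 9 purine genes (80.2), -0.07 for 22 genes of the heterochromatin machinery (31.2), -0.09 for 6 reporter and marker loci (12.3) and 0.01 for 10 meiotic genes (62.9). Of the 7 histone genes 6 lay above 0, so the negative value with at least 5 probes rests on the few genes left. The 42 subtelomeric genes had a median of -0.49, below each random list. Of the regions, centromeres were higher by 0.34 (percentile 99.96; Cy5 part 0.55, Cy3 part 0.23; 0.12 with normexp and 0.70 with equal MAD), the mating-type region by 0.20 (91.5) and rDNA ends by 1.12, above each random set, whereas Tf2 stood at -0.63 and subtelomeres at -0.24 (Cy5 part -0.08, Cy3 part 0.18; -0.0798 with equal MAD), below each of them, and tRNA gene probes at 0.04 (48.6).

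Domains extended these gene values. There were 157 domains of higher and 58 of lower H3-T7. The 5 strongest higher ones lay at the left rDNA end of chromosome III (3001 to 14760, mean 1.22), over ecl3, pho84 and pho1 (II, 4443301 to 4451460, 0.99), over pma1, the plasma membrane proton pump (I, 3866701 to 3873060, 1.04), over rad26 and atd1 (I, 4448701 to 4454160, 0.89) and over tlh1, a telomere-linked helicase gene (I, 601 to 7860, 0.70). The 5 strongest lower ones all lay near an end of chromosome I or II, such as 30601 to 39960 on I with ftm1 and ftm2 (-0.89), 33001 to 36360 on II with SPBC1348.12 (-1.23) and 5514601 to 5519160 on I with yhb1 and SPAC869.01 (-0.91). The number of genes in each direction depended on the starting signal, with 273 higher and 205 lower by normexp.

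The comparison of clr3-CDx2 ON with clr3-CDx2 OFF asks the same of cells with the altered deacetylase gene. The genes with the lowest values included a pair on either side of ura4, the orotidine phosphate decarboxylase gene: mug135 was lower by 2.36-fold (-1.24, SD 0.24 over 5 probes) and SPCC330.07C by 1.95-fold (-0.96, SD 0.29 over 7 probes). Each lay in a domain among the 5 strongest lower ones, 109801 to 113460 on III with SPCC330.03C and mug135 (-1.13, 12 probes) and 120001 to 123360 on III with SPCC330.07C (-1.13, 12 probes). Over 20 kb either side of ura4 the mean was -0.34 (percentile 0.35) against -0.12 in wt (5.73), and ura4 itself stood at -0.40 and in wt at -0.26. Over the probes of both domains the mean was -1.13 in clr3-CDx2 and -0.34 in wt, and the Cy3 input differed by 0.18 and 0.15. These probes were chosen by their low values in clr3-CDx2, so a smaller difference in wt is partly fixed by the choice. On them clr3-CDx2 minus wt was 0.26 in OFF and -0.53 in ON. Around ade6, 20 kb either side, the means were -0.07 (13.6) and in wt -0.15 (2.32).

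**Figure D2:**
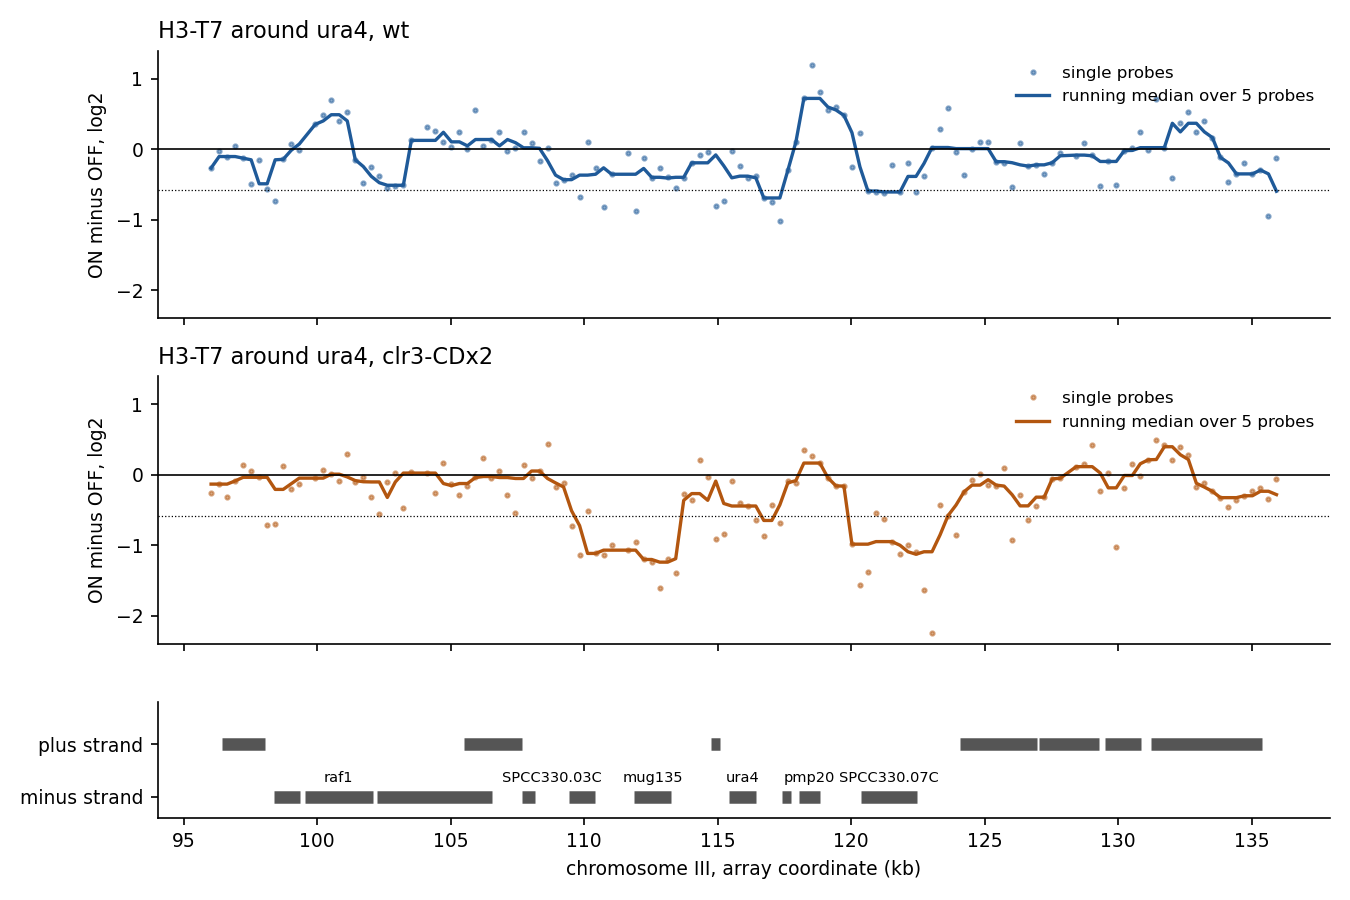
ON minus OFF log2 ratio of H3-T7 for each probe (points) and its running median over 5 probes (lines) against the array coordinate of chromosome III in kb, for wt and clr3-CDx2, with genes below and a dotted line at a 1.5-fold lower ratio. In clr3-CDx2 the line stays below it from 109801 to 113460 and from 120001 to 123360.

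Outside the ura4 region, other low genes of clr3-CDx2 ON were SPBPB8B6.02C (-1.11), SPAC869.01 (-1.08) and nas6, a proteasome assembly factor gene (-0.88). Among the highest were fba1 at 1.17, SPCC162.02C at 1.10, bsu1, a plasma membrane transporter gene, at 1.09 and thi201 at 0.96. In all, 71 genes were at least 1.5-fold higher and 39 lower, 8 of the lower ones subtelomeric. List medians were 0.53 for thiamine-repressed genes (percentile 99.99), 0.61 for phosphate genes (99.96), 0.43 for heat shock genes (92.4), 0.35 for histone genes (96.7; -0.0625 with at least 5 probes per gene), 0.21 for ribosomal protein genes (above each random list), 0.23 for purine genes (99.2), -0.05 for the heterochromatin machinery (29.7), -0.05 for reporter and marker loci (16.3), 0.15 for meiotic genes (97.6) and -0.18 for subtelomeric genes (0.08). Here too 6 of 7 histone genes lay above 0, and the value with at least 5 probes rests on few of them. The mating-type region was higher by 0.38 (99.3) and holds a domain from 2130001 to 2138160 on II with mat3-Mc (0.73). The rDNA ends were higher by 0.66, above each random set, while Tf2 stood at -0.23 (0.18), subtelomeres at -0.08 (1.72), centromeres at 0.10 (90.3; -0.0213 with normexp) and tRNA gene probes at 0.07 (91.5). The subtelomeric list median was 0.0299 with at least 5 probes per gene and 0.14 on probes with no f or m suffix, and with normexp the counts were 316 higher and 109 lower.

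Domains called in one genotype were read in the other. The 157 domains higher in wt ON averaged 0.42 in clr3-CDx2, with 149 on the same side, and the 58 lower ones averaged -0.40, with 54 on the same side. Of the 100 higher and 41 lower domains of clr3-CDx2, 96 and 38 lay on the same side in wt, with means of 0.56 and -0.41. None of 10000 random sets lay as far in any of these 4 readings. Across genes the differences of the genotypes correlated with r = 0.51 and rho = 0.45 over 4601 genes, which are not independent replicates. Genes at least 1.5-fold higher in both genotypes numbered 38, against 1.62 by chance, among them fba1, pma1, adh1, tdh1, pho84, pho1, thi4 and bsu1. Those lower in both numbered 12, against 0.670 by chance, among them fah1, grt1, ftm2, ftm5 and SPAC869.01. Of 14 overlapping pairs of lower domains, 3 lay over 100 kb from a chromosome end, at trs130 (III, 1824301 to 1827360 in wt), vps1301 (II, 3794101 to 3796560 in wt) and SPCC330.07C (III, 120601 to 121860 in wt).

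Limma, with both genotypes, found 281 genes that rose and 182 that fell in ON (600 and 479 at an unadjusted p below 0.05). The strongest were fba1 (1.38, SE 0.13, adjusted p = 6.26e-17), SPBC530.07C (1.22), lsd90 (1.11), pho1 (1.08), adh1 (adjusted p = 7.36e-10), SPCC162.02C, SPAC8E11.10 (0.97), SPBC23G7.10C (0.96), sua1 (sulfate adenylyltransferase, 0.96) and tdh1 (0.93). Among those that fell were fah1 (-1.16, SE 0.13, adjusted p = 1.26e-12), SPAC869.01 (-1.08), SPAC977.18 (-0.88), grt1 (-0.86), mug135 (-0.83), SPBPB8B6.02C (-0.82), ftm1 (-0.80), SPBPB2B2.18 (-0.79), ftm5 (-0.77) and ftm2 (-0.73). Of 9 thiamine-repressed genes 5 rose (6 rose and 1 fell adjusted over the list alone), of 7 histone genes 5 rose (6 adjusted over the list alone), of 9 heat shock genes 4 rose (9 adjusted over the list alone), and of 3 phosphate genes 2 rose (3 adjusted over the list alone). Of 54 ribosomal protein genes 11 rose (22 adjusted over the list alone). Of 42 subtelomeric genes 18 fell and 5 rose, tlh1 by 0.61 (23 and 6 adjusted over the list alone). In the heterochromatin machinery 3 of 22 fell, also adjusted over the list alone: mit1 (-0.51), the remodeler of SHREC, hrr1 (-0.49), an RNA helicase of RNA interference, and dcr1 (-0.43), Dicer. Of 6 reporter and marker loci leu1 rose by 0.50 (1 rose and 1 fell adjusted over the list alone). Its Cy3 part was -0.27 in wt and -0.14 in clr3-CDx2. No purine gene and no meiotic gene changed by limma, over all genes or adjusted over the list alone (3 and 0 at an unadjusted p below 0.05).

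The 281 and 182 rest on 1 residual degree of freedom per gene and on 150 prior degrees of freedom pooled across genes. With normexp the prior held 5.90, and the smallest adjusted p of limma was 0.0293. Without a term for genotype, limma called 53 and 20. Without that term and without 1 array in turn it called 19 to 159 and 6 to 97; since 3 arrays leave no residual for both terms, 2 choices change at once there. They were 34 and 10 with normexp, where fba1 did not pass (0.40), 157 and 139 with scaling to equal MAD, and 98 and 40 without detrending.

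The separate channels divided the ON differences. For the 38 genes higher in both genotypes the median difference was 0.83 in wt, with 0.60 in the Cy5 and -0.21 in the Cy3 signal, and 0.71 in clr3-CDx2, with 0.70 and 0.00 (a Cy3 value of -0.0045). The 105 genes higher in wt, read in clr3-CDx2, had a median Cy5 difference of 0.53 (SD 0.27 over genes, 104 above 0), and the 71 higher in clr3-CDx2, read in wt, 0.42 (SD 0.32, 69 above 0). The thiamine-repressed genes in wt stood at -0.16 in Cy5 and -0.44 in Cy3, and in clr3-CDx2 at 0.22 and -0.28. Ribosomal protein genes in wt stood at 0.02 and -0.17, and in clr3-CDx2 at 0.18 and 0.02. The rDNA ends in clr3-CDx2 stood at 0.08 in Cy5 and -0.55 in Cy3, and in wt at 0.71 and -0.40. Tf2 probes in wt stood at -0.15 and 0.50. Some single genes carried large Cy3 parts, such as lsd90 in wt (-0.84), eno101 in wt (-0.61) and nmt1, the thi3 gene of thiamine synthesis, in wt (-0.77). Limma on the Cy3 channel over both genotypes called 0 genes that rose and 1 that fell (91 and 56 at an unadjusted p below 0.05), thi2, a gene of thiamine synthesis, at -0.85 (adjusted p = 0.0482).

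**Figure D3:**
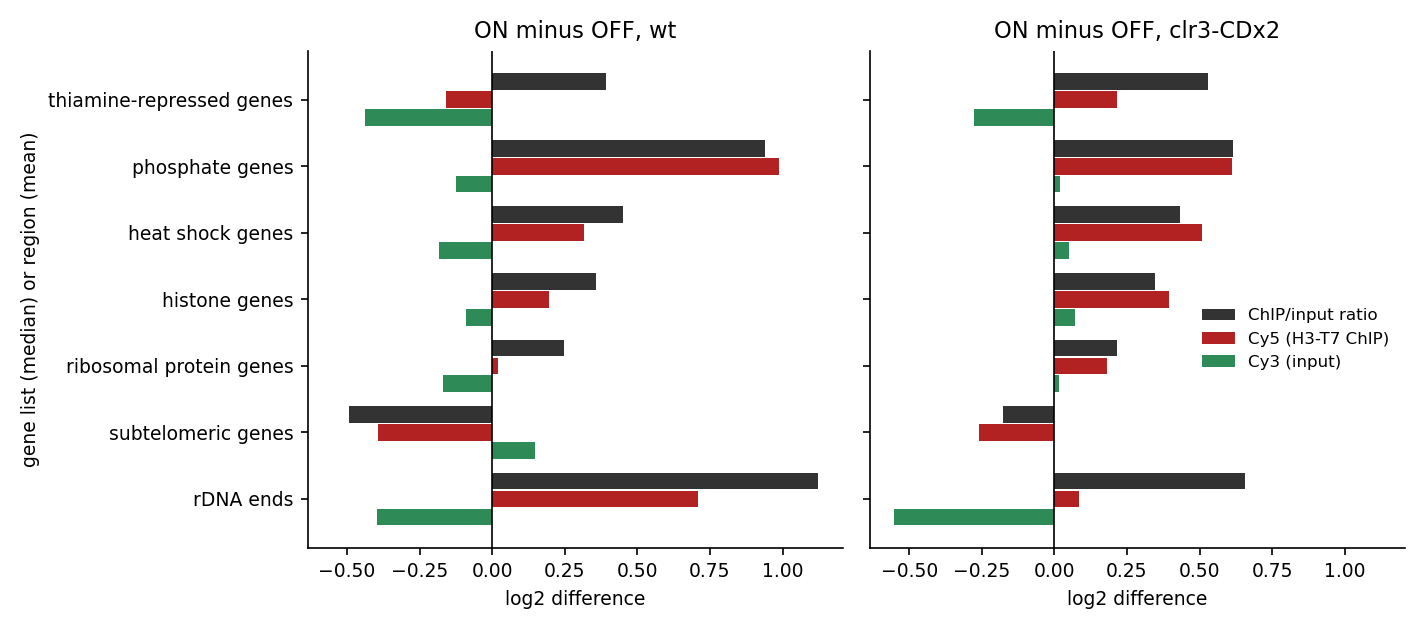
ON minus OFF difference (log2, horizontal axis) of the ChIP over input ratio, of the Cy5 ChIP channel and of the Cy3 input channel, for 6 gene lists (medians) and the rDNA ends (mean), in wt and in clr3-CDx2. Thiamine-repressed genes in wt stand at 0.39 for the ratio, -0.16 for Cy5 and -0.44 for Cy3.

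The comparison of clr3-CDx2 OFF with wt OFF asks what the altered clr3 does without tethering. H3-T7 was higher in clr3-CDx2 near the ends of chromosomes I and II. The genes eno102 (a second enolase gene, 1.61, 3.06-fold, SD 0.54 over 5 probes), cmt2 (1.48), SPAPJ695.02 (1.38), SPAC212.04C (2.30-fold), ght7 (a hexose transporter gene, 1.12) and say1 (1.06) were highest. Subtelomeres were higher by 0.34 (percentile 99.96, Cy3 part -0.01), with 0.65 at the left end of II, 0.52 at its right end, 0.27 at the left end of I and -0.00 at its right end (a value of -0.0019). The strongest domains covered eno102 and cmt2 (II, 57601 to 69360, 1.16), SPAPJ695.02 (I, 70801 to 81960, 1.10), ght7 (II, 37501 to 44760, 1.27), SPAC212.04C (I, 20401 to 29160, 1.08) and SPBPB10D8.05C (II, 90301 to 100860, 0.88). The clr3 gene itself was higher by 0.58, with -0.12 in its Cy3 part.

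In OFF cells 26 genes were at least 1.5-fold higher and 10 lower in clr3-CDx2, and 67 domains were higher and 1 lower, at pdc102 (I, 5548801 to 5551260, -0.93). The lower genes were led by pdc102, a pyruvate decarboxylase gene (-0.76), ies4 (-0.72, Cy3 part 0.44), SPAC186.08C (-0.68), gid2 (-0.66) and erv25 (-0.64). Centromeres were higher by 0.24 (98.4; Cy5 part 0.36, Cy3 part 0.12; 0.0653 with normexp and 0.35 with equal MAD), while the mating-type region stood at 0.00 (-0.0012), rDNA ends at 0.13 (91.8), Tf2 at -0.15 (0.31; Cy5 part 0.06, Cy3 part 0.21) and tRNA gene probes at 0.06 (95.8). List medians were 0.15 for subtelomeric genes (above each random list), -0.08 for ribosomal protein genes (2.63), -0.13 for histone genes (6.11), -0.11 for purine genes (14.0), -0.07 for the heterochromatin machinery (21.6), -0.09 for reporter and marker loci (24.3), -0.05 for heat shock genes (24.3), -0.03 for thiamine-repressed genes (42.4), 0.01 for phosphate genes (61.7) and -0.01 for meiotic genes (67.4). The split of higher and lower genes depended on the starting signal: 72.2% of the 1.5-fold genes were higher, against 48.8% (61 and 64) with normexp.

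The comparison of clr3-CDx2 ON with wt ON asks the same under tethering. Subtelomeres were again higher in clr3-CDx2, by 0.50, above each of 10000 random sets, with -0.20 in the Cy3 part, and each end was higher (0.33 to 0.74). The highest genes were say1 (1.12), clr3 (1.08, Cy3 part -0.11), SPBPB2B2.05 (1.04), cta3 (an ion-transporting ATPase gene, 0.96), cmt2 (0.92), SPAC186.06 (0.90), SPBPB10D8.02C (0.88) and gal10 (UDP-glucose epimerase, 0.88, on the same 11 probes as tgd1). Lower genes were eno101 (-0.86, Cy3 part 0.72), fba1 (-0.85, Cy3 part 0.49), cwf26 (-0.78), mug166 (-0.75), pho842 (-0.74), mug135 (-0.73) and ole1 (fatty acid desaturase, -0.71). The strongest higher domains covered eno102 and cmt2 (II, 57901 to 70260, 0.87), fub2, nrg1 and say1 (II, 4455301 to 4464060, 1.09) and pan5 (II, 4473001 to 4482960, 0.99).

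Counts in ON were 43 genes at least 1.5-fold higher, 15 of them subtelomeric, and 24 lower, with 50 higher and 29 lower domains. Subtelomeric genes had a median of 0.47 (40 of 42 above 0). Other medians were -0.10 for ribosomal protein genes (0.73; 0.0193 with at least 5 probes per gene, 0.00182 on probes with no f or m suffix), -0.19 for reporter and marker loci (2.57), -0.22 for phosphate genes (9.64), -0.11 for histone genes (13.2), -0.04 for heat shock genes (26.0), -0.04 for purine genes (34.5), -0.01 for the heterochromatin machinery (59.3), 0.07 for thiamine-repressed genes (76.0) and 0.06 for meiotic genes (85.2). The mating-type region was higher by 0.19 (96.6), Tf2 by 0.25 (99.6) in ratio with lower signals in both channels (Cy5 -0.34, Cy3 -0.59) and tRNA gene probes by 0.09 (99.9), centromeres stood at 0.01 (64.4), and rDNA ends at -0.34, below each random set. The region around ura4 stood at -0.18 (0.43), against 0.04 (73.2) in OFF. The counts were 140 and 70 with normexp and 27 and 14 with scaling to equal MAD.

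The subtelomeric difference reached inward from the ends. In 25 kb steps from the ends of chromosomes I and II the clr3-CDx2 minus wt difference was 0.15, 0.51, 0.69, 0.52, 0.28 and 0.13 in OFF and 0.42, 0.56, 0.47, 0.44, 0.23 and 0.11 in ON, and it was 0.00 (-0.0035) and 0.03 from 150 to 175 kb. The 67 domains higher in OFF averaged 0.54 in ON (62 on the same side), and the 50 higher in ON averaged 0.70 in OFF (45 on the same side), with none of 10000 random sets as far. The 29 lower in ON averaged -0.01 in OFF (18 on the same side, 2776 random sets as far), and the single lower domain of OFF stood at 0.41 in ON. All 13 genes at least 1.5-fold higher in both states (0.243 by chance) lay 23.1 to 109 kb from an end, as listed for SPAC212.04C, say1, ght7, SPBPB2B2.05, nhe1, fub2, eno102, SPBPB21E7.11, cmt2, SPAPJ695.02, SPBPB10D8.01, SPBPB10D8.05C and alr2. No gene was 1.5-fold lower in both. Across all 4601 genes, which are not independent replicates, the differences of the 2 states correlated with r = 0.18 and rho = 0.10.

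**Figure D4:**
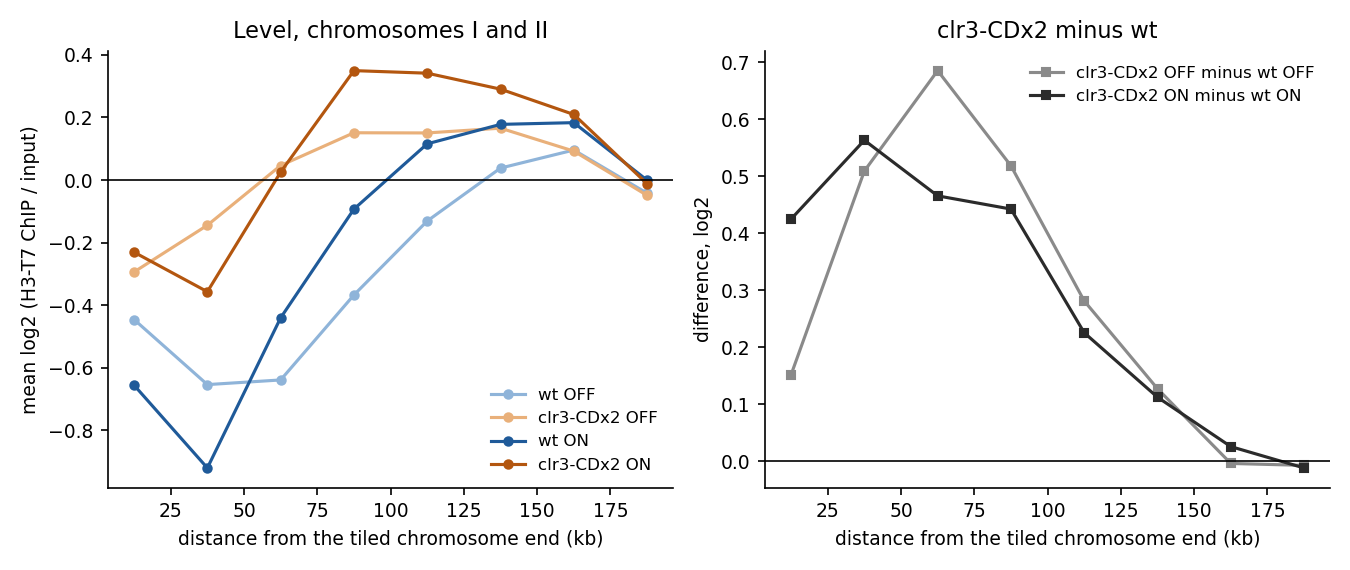
Mean log2 ratio of H3-T7 ChIP over input per array (left) and clr3-CDx2 minus wt difference (right) against the distance in kb from the tiled ends of chromosomes I and II, in 25 kb steps. The difference is highest at 0.69 from 50 to 75 kb in OFF and at 0.56 from 25 to 50 kb in ON.

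Limma, with both tethering states, found 43 genes that rose and 17 that fell in clr3-CDx2 (167 and 237 at an unadjusted p below 0.05). The strongest were eno102 (1.23, SE 0.13, adjusted p = 2.01e-13), cmt2, say1 (1.09), SPAPJ695.02 (1.03), SPAC212.04C (0.98), SPBPB2B2.05 (0.96), ght7 (0.87), SPBPB10D8.01 (0.86), clr3 (0.83) and SPBPB21E7.11 (0.79). Of the genes that fell, fba1 (-0.64, adjusted p = 2.82e-04), rpl101 (-0.57), chp1 (-0.57), mug166 (-0.56), cys11 (-0.53), ilv1 (-0.53), SPCC417.12 (-0.52), pdc101 (-0.50), dic1 (-0.48) and prp38 (-0.48) had the smallest adjusted p. The value of chp1, the chromodomain protein of the RITS complex, rests on 2 of its 12 probes: without them the difference was -0.08 in OFF and -0.08 in ON, and on these 2 the Cy3 input differed by 1.803 in OFF and 1.19 in ON. These probes were singled out after their values were seen. In the fit on the Cy3 channel fba1 differed by 0.35 and cys11 by 0.31, so part of their fall in ratio lies in the input. Of 42 subtelomeric genes 16 rose and 0 fell (23 and 1 adjusted over the list alone). In the heterochromatin machinery clr3 rose and chp1 fell, also adjusted over the list alone, and of 54 ribosomal protein genes 1 fell, as it did adjusted over the list alone. No other list had a member that changed over all genes by limma (thiamine-repressed 1, histone 1, meiotic 1, heat shock 1 and purine, phosphate and marker genes 0 at an unadjusted p below 0.05), and adjusted over the list alone 1 histone gene fell. Limma without a term for tethering called 0 genes in either direction (58 and 50 at an unadjusted p below 0.05), as did limma with normexp (154 and 154), and limma without detrending called 15 and 0 (149 and 191). Leaving out an array as well as the term for tethering gave 0 and 0 without wt OFF or wt ON (93 and 100, 74 and 60 at an unadjusted p below 0.05), 17 and 1 without clr3-CDx2 OFF and 5 and 1 without clr3-CDx2 ON, so these counts cannot be put down to the array alone.

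The difference of the tethering differences, clr3-CDx2 minus wt, asks whether the response to tethering depends on clr3, and could not be tested with 1 array per group. Genes with the most negative values were erd2 (an endoplasmic reticulum retention receptor gene, -1.02), nas6 (-1.02), pho842, eno101 (Cy3 part 0.95), mug135 (-0.82), cwf26 (-0.82), atd1 (-0.80) and pcn1 (PCNA, -0.78). The most positive were SPAC227.17C (1.28, SD 1.31 over 3 probes, Cy3 part -0.74), pdc102 (1.17), SPAC186.08C (1.13), gid2, pts1, gal10 (0.94) and mad2, a spindle checkpoint gene (0.87). The region around ura4 stood at -0.22 (0.66), centromeres at -0.23 (-0.14 with normexp) and rDNA ends at -0.47 (both below each random set), and subtelomeres at 0.16 (Cy5 part -0.03, Cy3 part -0.18; 0.0487 with equal MAD), Tf2 at 0.41 (Cy5 part -0.40, Cy3 part -0.80; both ratios above each random set), the mating-type region at 0.19 (98.4) and tRNA gene probes at 0.03 (90.6). The strongest domains were at pdc102 (I, 5547001 to 5551260, 1.11) and ctt1, the catalase gene, with cox14 (III, 57301 to 60960, 0.92), and of the lower ones at 5519101 to 5522460 on I (-1.03) and ght7 (II, 40201 to 42960, -1.17). In all, 74 genes were at least 1.5-fold higher and 55 lower, with 64 higher and 103 lower domains. The gene counts were 307 and 149 with normexp (67.3% higher, against 57.4%) and 32 and 32 with at least 5 probes per gene. List medians were 0.24 for subtelomeric genes, above each random list, -0.33 for phosphate genes (2.73), 0.16 for thiamine-repressed genes (92.9), and between -0.09 and 0.06 for the other 7 lists.

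The input of the same probes was compared between arrays. The Cy3 signal of ura4 differed by 0.03 (wt) and 0.01 (clr3-CDx2) between ON and OFF, and that of ade6 by -0.04 and 0.13. By limma 0 genes rose and 0 fell with genotype in Cy3 (80 and 46 at an unadjusted p below 0.05). The fit takes a difference on 1 array as noise, and single pairs held larger values: lsd90 was higher in clr3-CDx2 ON than in wt ON by 1.02. The largest, for ubx4 at 2.43 in clr3-CDx2 OFF minus wt OFF and 2.41 in wt ON minus wt OFF, comes from 1 of its 5 probes, low in both channels of wt OFF (Cy5 -10.01, Cy3 -10.84).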

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

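All tests of explanations given here were chosen after the patterns were seen; only for the subtraction of the mitochondrial ratio at the subtelomeres was the prediction written before the value of the test was known.

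The mean difference of the rDNA ends of chromosome III had opposite signs in the tethering states. The clr3-CDx2 minus wt difference was 0.13 in OFF (SD 0.59 over probes; Cy5 0.02, Cy3 -0.12) and -0.34 in ON, and the difference between these was not tested. The sign in OFF is that of the mean alone: 59.6% of the probes lay below 0 in OFF and 81.9% in ON. The left end stood at 0.04 in OFF and -0.40 in ON. The right end (29 probes) stood at 0.35 in OFF (SD 0.69) and -0.19 in ON.

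A signal also appeared outside the measurement compared in the report. In the Cy3 input, thi2 stood at -0.96 (ON minus OFF) in wt and at -0.74 in clr3-CDx2. Probes of the pNSU clones, contigs of the array whose content is not given in the sources used here, were higher in ON by 0.60 in wt and 0.19 in clr3-CDx2.

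Lower H3-T7 on both sides of ura4 in clr3-CDx2 ON cells was a local pattern, in separate domains within 109801 to 123360 on III. In wt a lower domain was also called over SPCC330.07C (120601 to 121860, -0.53). More input DNA at the locus is argued against by a Cy3 difference of 0.18 over the clr3-CDx2 domains, which averaged -1.13. Detrending of 1 channel is argued against by a mean of -1.11 without it. Tethering and the medium cannot be told apart, since 0 arrays separate them, and the site of the reporter is not given in the sources used here. Both stay open.

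Higher subtelomeric H3-T7 in clr3-CDx2, as a mean over 50 kb at each end of chromosomes I and II, was present in both tethering states. The pNSU clone probes, tiled apart from the chromosomes, are not part of this mean. They were lower in clr3-CDx2 than in wt by -0.31 in ON and higher by 0.09 in OFF. On the 283 probes with no f or m suffix the smaller of the 2 differences was 0.43, and Cy5 differed by 0.39 in OFF and 0.35 in ON. These Cy5 values argue against input DNA as the whole cause. Repeat probes cannot be excluded in this way, because the meaning of the suffix is not given in the sources used here. Non-specific background of the size of the mitochondrial ratio, 3.86% to 7.70% of the array median, did not account for the difference. Once it was subtracted the smaller difference was 0.36. So small a subtraction could hardly move the difference, and in clr3-CDx2 ON that ratio reflects the input channel. Background of a larger size was not tested. A strain difference other than clr3 cannot be told apart from the altered clr3, with 0 further wt strains among the arrays. The altered clr3 stays open as an untested explanation.

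Higher ratios in ON at the genes called higher, at thiamine-repressed and ribosomal protein genes and at rDNA ends divide into parts. For the genes called higher in 1 genotype, loss of input DNA as the whole cause is argued against by a median Cy5 difference of at least 0.42 in the genotype not used for the call (at least 0.60 for the 38 genes called in both, themselves chosen by their ratio). GC content as the whole cause is argued against by a difference of at least 0.66 in those 38 with its trend removed, though they were chosen by their ratio. With the trend removed, 74 genes were higher in wt, against 105, and 54 in clr3-CDx2, against 71. A part for GC content thus stays open. For thiamine-repressed genes in wt the Cy5 difference was -0.16, for ribosomal protein genes in wt 0.02, and for the rDNA ends in clr3-CDx2 0.0846, so that for these parts the higher ratio is consistent with less input DNA recovered, while the rDNA ends in wt (0.71) and, in clr3-CDx2, thiamine-repressed (0.22) and ribosomal protein genes (0.18) had higher Cy5 as well. Tethering and the medium change together in every ON array, so a biological cause of the first part stays open between them.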

How the results depend on the processing

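In all, 777 results were recomputed under 26 alternatives, giving 11242 values. The series matrix values and probes well above background left every count of 1.5-fold genes as it was. Causes of the moves below were not tested, except that higher thresholds and higher probe minimums leave fewer genes by construction. The alternatives named as chosen after seeing the data are marked so. Signal stood far above background on all arrays, so depth limits few probes.

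With normexp, centromeres stood at -0.91 in wt OFF, -0.85 in clr3-CDx2 OFF, -0.79 in wt ON and -0.87 in clr3-CDx2 ON, rDNA ends at -2.55, -2.37, -1.17 and -1.75, and subtelomeres in wt ON at -0.91. Higher and lower genes were 273 and 205 (wt ON minus OFF), 316 and 109 (clr3-CDx2 ON minus OFF), 61 and 64 (genotype in OFF), 140 and 70 (genotype in ON) and 307 and 149 (difference of differences). Subtelomeres differed by 0.58 in ON, and domains called in one genotype and read in the other averaged 0.51 (wt higher), -0.30 (wt lower), 0.53 (clr3-CDx2 higher) and -0.48 (clr3-CDx2 lower). The centromere difference fell to 0.12 in wt ON minus OFF and to 0.0653 for genotype in OFF, and reversed to -0.0213 in clr3-CDx2 ON minus OFF, and fba1, the gene with the smallest adjusted p for tethering, did not pass in limma at 0.40. Limma called 34 and 10 genes for tethering and 0 and 0 for genotype (566 and 308, 154 and 154 at an unadjusted p below 0.05).

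With loess, centromeres stood at -1.43 in wt OFF, -1.144 in wt ON and -1.136 in clr3-CDx2 ON, 43 genes were higher in clr3-CDx2 ON, and its higher domains read in wt averaged 0.64. With equal MAD, centromeres stood at -1.85 in wt OFF, -1.50 in clr3-CDx2 OFF and -1.13 in clr3-CDx2 ON, and rDNA ends at -2.22 in wt OFF and -1.97 in clr3-CDx2 OFF. Then 46 genes were higher in clr3-CDx2 ON, 23 lower by genotype in OFF, and 27 and 14 higher and lower by genotype in ON. Subtelomeres differed by 0.40 in OFF, domains read in the other genotype averaged 0.39 (wt higher), 0.72 (clr3-CDx2 higher) and -0.34 (clr3-CDx2 lower), and limma called 157 genes that rose with tethering.

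At 1.3-fold, higher and lower genes were 359 and 319, 340 and 199, 97 and 113, 172 and 156, and 373 and 261 in the same order of comparisons, and domains read in the other genotype averaged 0.28, -0.24, 0.37 and -0.27, in the order given for normexp. At 2-fold they were 13 and 7, 4 and 3, 7 and 0, 3 and 0, and 4 and 3, and domains averaged 0.67, -0.46, 1.12 and -0.63. Running medians over 3 and 9 probes gave 0.59 and 0.60 for higher domains of clr3-CDx2 read in wt.

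With at least 5 probes, 40 genes were lower in wt ON, 21 lower in clr3-CDx2 ON, 13 and 5 higher and lower by genotype in OFF, 19 and 11 in ON, and 32 and 32 in the difference of differences, and limma called 19 that rose by genotype. The histone list stood at -0.22 in wt and -0.0625 in clr3-CDx2. This minimum drops genes without changing their values, and 6 of 7 histone genes lay above 0 in both genotypes. The negative medians thus rest on the few histone genes left. The subtelomeric list in clr3-CDx2 reversed to 0.0299 and the ribosomal protein list by genotype in ON to 0.0193. With 1 probe, 113 genes were higher in clr3-CDx2 ON, and 45 and 69 higher by genotype in OFF and ON. With gene medians, 16 were lower by genotype in OFF, 42 in ON, and 124 and 87 higher and lower in the difference of differences, and limma called 121 that fell with tethering and 9 with genotype.

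For limma, no term for the other factor gave 53 and 20 for tethering and 0 and 0 for genotype (58 and 50 at an unadjusted p below 0.05), and probes as the unit gave 1746 and 1086, and 590 and 60. With 3 arrays both terms would leave no residual degrees of freedom, so where 1 array was left out the term for the other factor was left out too. Leaving out both gave 19 to 159 and 6 to 97 for tethering and 0 to 17 and 0 to 1 for genotype, where a lone array is assumed to vary like the others. Limma then called 0 and 0 for genotype without wt OFF (93 and 100 at an unadjusted p below 0.05) and without wt ON (74 and 60), as it did with all 4 arrays and no term for tethering. The genotype difference of fba1 ranged from -1.44 to 0.15 in these fits, reversed without wt ON, where the other wt array is OFF and the tethering difference enters the estimate. None of these moves can be put down to the array alone.

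For named genes, under alternatives chosen before the data were examined, 3902 values stayed within the SD over the probes of the gene and 155 moved. Of the moves 107 came with normexp, where 358 values stayed. The series matrix values and the probe minimums cannot move the value of a gene, so the 3902 include values that were fixed. Counts and regions were judged by other yardsticks, so the shares cannot be compared with theirs. In limma 2281 values of named genes kept their side of the threshold, 234 no longer passed, 14 came to pass and 1 reversed.

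Chosen after seeing the data, probes with no f or m suffix gave centromeres of -1.89, -1.61, -1.71 and -1.52, subtelomeres of -0.66 in wt OFF, a subtelomeric difference of 0.43 in OFF and 0.53 for higher domains of clr3-CDx2 read in wt. There the subtelomeric list in clr3-CDx2 reversed to 0.14 and the ribosomal protein list by genotype in ON to 0.00182. Also chosen after seeing the data, GC removal gave 6 genes lower by genotype in OFF and 0.53 and -0.35 for higher and lower domains of clr3-CDx2 read in wt, signals without detrending gave limma counts of 98 and 40 for tethering and 15 and 0 for genotype (149 and 191 at an unadjusted p below 0.05), and genes placed 150 bp to the right gave 11 that fell by genotype.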

Other observations

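The mitochondrial probes, which carry no histones, stood at 4.04% of the array median ratio in wt OFF, 4.76% in clr3-CDx2 OFF, 3.86% in wt ON and 7.70% in clr3-CDx2 ON. From OFF to ON in clr3-CDx2 their Cy5 signal differed by -0.21 and their Cy3 signal by -0.90, so the higher ratio comes from the input channel. The contig of the mating-type region, tiled apart from the chromosomes, stood at -0.47, -0.45, -0.14 and 0.00 (0.0027) on the same arrays, so that it was higher in ON by 0.33 in wt and by 0.46 in clr3-CDx2. The pNSU clone probes stood at -1.09 in wt OFF, -0.49 in wt ON and -0.81 in clr3-CDx2 ON. Their clr3-CDx2 minus wt difference was 0.09 in OFF, with 69.9% of 123 probes above 0. In ON it was -0.31, with 88.6% of the probes below 0, opposite in sign to the subtelomeres.

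Near chromosome ends the ON minus OFF difference changed sign with distance. From 0 to 50 kb it was -0.21 and -0.27 in wt per 25 kb step, and from 50 to 125 kb it was 0.20, 0.27 and 0.25. In clr3-CDx2 it was 0.06, -0.21, -0.02, 0.20 and 0.19 over the same steps. For the probes from 0 to 50 kb in wt, the Cy5 part was -0.08 and the Cy3 part 0.18. Most of the lower ratio there thus lay in the input. The input of wt ON stood slightly apart, with correlations across probes of 0.955 to 0.966 with the other arrays, against 0.967 to 0.983 among those.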
